A study of Mus musculus with 4 samples.

How the data were processed

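RNA bound by MOV10 was measured by eCLIP in N2A mouse neuroblastoma cells. Per the labels' protocols, frozen cell pellets were processed by a contract laboratory with an anti-MOV10 antibody after the published eCLIP method without changes, and 4 libraries were made, 2 immunoprecipitates and 2 inputs. Nothing in the labels says whether the replicates came from separate cultures. The values used came from 1 peak list of the whole series, whose name marks it as immunoprecipitate against input after an irreproducible discovery rate (IDR) step. Values per library were not analysed here. How the replicates were combined, the aligner, the peak caller, the annotation and the thresholds are not given in the sources used here. The genome builds mm10 and GRCm38.p6 are named in the submitters' processing notes.

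The deposited list gave a position, a strand and 2 values per peak, with no header. The first value was read as the −log10 p of each peak computed by the authors, and the second as the log2 fold enrichment deposited by the authors. Both readings rest on the values themselves, which start just above 3 in each column and, in the first, stop at 400 for 84 peaks, and on the order of columns in published eCLIP peak files. If the reading of either column is wrong, the statements on strength would change, while those on position would not. These values were used only to describe, rank and filter peaks within the list. The number of reads behind a peak, and so its counting error, was not known.

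Start positions were converted to count from 1. Genes came from a table of GRCm38.p6 gene spans that held no strand, exons or untranslated regions, and no genome sequence was used here. To check that the coordinates of the list and of the table match, all peaks were shifted along the chromosomes. Unshifted, 97.6% had their midpoint in a protein-coding gene, against 62.9% after a shift of 100000 nt, 47.0% after 1000000 nt and 38.8% after 5000000 nt. Peaks with their midpoint in exactly 1 gene span were assigned to it. Peaks with their midpoint in several overlapping genes were left out of gene statistics, since the table gives no strand to separate them. The direction of each gene was taken from the strand of its peaks. Of 1207 genes with 2 or more peaks, 0 had peaks on both strands.

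Tests planned before the data were examined on transcript regions, on position along the 3′ untranslated region, on GC content, G-quadruplex motifs, folding energy and microRNA seed sites needed exons or sequence and were not run. In their place, the distance of each peak midpoint to either end of its gene was used. The 5 kb window, the minimum span of 15 kb and the assignment to single genes were set after the data had been seen. The share of peaks within the window was compared with 1000 random placements of each peak within its own gene span, and its 95% interval came from 2000 bootstrap draws of genes. The difference in median log2 fold enrichment between peaks near the 3′ end and elsewhere was tested by 100000 permutations of single peaks, which are not independent within a gene, and its interval came from the same bootstrap over genes. A version within genes permuted the positions of peaks inside each gene 2000 times.

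Written from general knowledge before the data were examined, 19 gene lists covered microRNA silencing, mRNA decay, RNA helicases, splicing and nuclear RNA-binding proteins, FMRP targets, cytoskeleton, adhesion and axon guidance, neuroblastoma lineage, cell cycle, ribosomal proteins, translation factors, oxidative phosphorylation, mitochondrially encoded genes, histones, small nuclear and nucleolar RNAs, long non-coding RNAs, chromatin regulators, interferon-stimulated genes and the ubiquitin system. Some genes stand in more than 1 list. For each list the members with a peak assigned to them were counted. Members whose only peaks lay where several genes overlap were not counted. These were 3 in the ubiquitin list, 2 among translation factors and at most 1 in any other list. The 10 lists with at least 5 members with peaks were compared with the other coding genes with peaks, by the median of the strongest log2 fold enrichment per gene (two-sided permutation test, 100000 resamples) and by the share of genes with a peak near the 3′ end (two-sided Fisher's exact test). The number of peaks per gene was compared in the same way, as a measure added after the data had been seen. Benjamini-Hochberg adjustment ran over the 10 lists within each measure, with a threshold of 0.05. The abundance of transcripts in the input was not known, so no list was compared between genes with and without peaks.

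Named genes followed a rule fixed before the data were examined, with its transcript regions replaced by position along the gene. It took the 8 coding genes with the strongest peak near the 3′ end, the 5 in the interior and the 4 near the 5′ end, up to 5 non-coding RNA genes, each peak with a −log10 p at or above the median of its class, and the 8 genes with most peaks. It also took up to 4 members with the strongest peak from each list with at least 3 members with peaks, and Mov10, Ago2, Fmr1, Upf1 and Malat1 in any case. The rule's part on introns was not used, and a few genes that the rule takes are not reported here. Further genes named outside this rule, such as other members of the microRNA silencing list, the members of lists with fewer than 3 genes with peaks, and the genes of the closing observations, were chosen after their values were seen.

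Both tests were tested on simulated data. With peaks placed at random in their genes, the placement test called 10 of 200 runs at the 0.05 threshold, and with a share of 0.05 of the peaks moved into the window it called 200 of 200. Simulated peaks were placed independently, as in the test itself, so these runs do not show its error rate for clustered peaks. The list test was judged by its unadjusted p at the same threshold. It called 3.0% of 200 runs with 12 members and no shift. At a log2 shift of 0.5 it called 38.0%, and at a shift of 1.0 it called 95.5%. With 5 members it called 15.0% and 66.0% at these shifts, and with 20 members 70.0% and 100.0%. Alternatives included stricter limits on log2 fold enrichment (at least 4) and −log10 p (at least 5), merging of peaks, the strongest peak per gene, the 5′ end of the peak in place of its midpoint, windows of 2 kb and 10 kb, assignment among coding genes alone and leaving out single list members. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.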

Results

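MOV10 is an RNA helicase that associates with Argonaute proteins and other RNA-binding proteins in the cytoplasm. Its RNA partners were mapped by eCLIP in N2A cells, a mouse neuroblastoma line. In eCLIP, proteins are crosslinked to RNA by ultraviolet light, a protein is immunoprecipitated with its crosslinked RNA fragments, and the fragments are sequenced next to a size-matched input. The series comprised 4 libraries, 2 from MOV10 immunoprecipitates and 2 inputs, and its title places the experiment beside RNA unfolding and AGO2-mediated silencing. The comparison addressed here was which transcripts, and which parts of them, were enriched in the immunoprecipitates over the inputs. The values analysed were those of a single list of reproducible peaks that combined both replicates, each with 2 values of the authors', taken here as the log2 fold enrichment of immunoprecipitate over input and the −log10 p. Each peak thus had 1 value over all libraries, so no standard deviation between replicates could be given for any gene, and the sequencing depth of the libraries was not known. Intervals below describe the spread over genes or peaks and do not measure the difference between cultures.

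MOV10 peaks lay almost entirely in protein-coding genes. The list held 12236 peaks, 6143 on the plus strand and 6093 on the minus strand, and 11207 of them (91.6%) had their midpoint in exactly 1 annotated gene. Of these single-gene peaks, 99.8% were in protein-coding genes, and they marked 1686 coding genes, 7.70% of the 21900 coding genes of the annotation. A further 755 peaks (6.17%) had their midpoint where several genes overlap and were not assigned, and 274 (2.24%) had it in no annotated gene span. No peak was listed on the mitochondrial chromosome, whose 37 genes were in the annotation. The median log2 fold enrichment was 3.71 (interquartile range 3.34 to 4.20), a 13.1-fold linear enrichment, and the highest was 6.93 (122-fold). The lowest was 3.001, so weaker binding was not represented and the lack of a peak in a gene is not evidence that it was unbound. Peaks were short, with a median of 74 nt (interquartile range 44 to 109), and many touched. Merging touching peaks left 8042 intervals, which covered 998241 nt.

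Peaks, with touching ones counted singly, were unevenly distributed among genes. The median coding gene with a peak held 3, while 484 genes (28.7%) held 1. The 10 genes with most peaks held 714 peaks (6.38% of the peaks in coding genes), and the top 100 held 30.8%. The largest number was 110, in Cbx5, which encodes the heterochromatin protein HP1α. Ttyh3, of the tweety family of membrane proteins, held 101, and Elavl1, which encodes the AU-rich-element-binding protein HuR, held 78. Tead1, a transcription factor of the Hippo pathway, followed with 68, the transcriptional coregulator gene Tcf20 with 65, and Pabpc1, the cytoplasmic poly(A)-binding protein gene, and the homeobox gene Hmbox1 with 60 each. Mib1, a ubiquitin ligase of Notch signalling, held 58. Peaks at the highest listed −log10 p of 400 numbered 84 over the whole list, 23 of them in Cbx5, 20 in Ttyh3, 11 in the neuronal growth gene Dpysl3 and 10 in Elavl1.

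Within genes, MOV10 peaks lay near the 3′ end. In the 1421 genes with a span of at least 15 kb, 8620 of 9978 peaks (86.4%, 95% bootstrap interval over genes 83.7 to 88.9) had their midpoint within 5 kb of the annotated 3′ end. Within 5 kb of the 5′ end there were 31 peaks (0.311%, interval 0.145 to 0.532). The median distance to the 3′ end was 1618 nt (interval 1514 to 1717), against 57494.5 nt to the 5′ end, and 58.8% of peaks lay within 2 kb of the 3′ end. By gene, 1292 had peaks within 5 kb of the 3′ end but not of the 5′ end, and 3 had the reverse. Another 12 had peaks within 5 kb of both ends and 114 of neither. Peaks farther inside the gene did not enter these counts. Of the 1295 genes with peaks near only 1 of the ends, 99.8% had them near the 3′ end (exact 95% interval 99.3 to 99.95). Random placement of each peak within its own gene span put 10.5% within 5 kb of the 3′ end, and the highest of 1000 placements reached 11.6% (two-sided permutation p = 0.002, the smallest that 1000 placements can give). Random placement used the whole span with introns, since exons and untranslated regions were not used here, so it is no reference for the mature mRNA. How much mature mRNA each end of a gene holds was likewise not taken into account. Peaks were also placed independently although they cluster, so the spread of the random placements is too narrow. With the strongest peak per gene alone the share was 90.0%, against 11.2% by random placement.

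**Figure D1:**
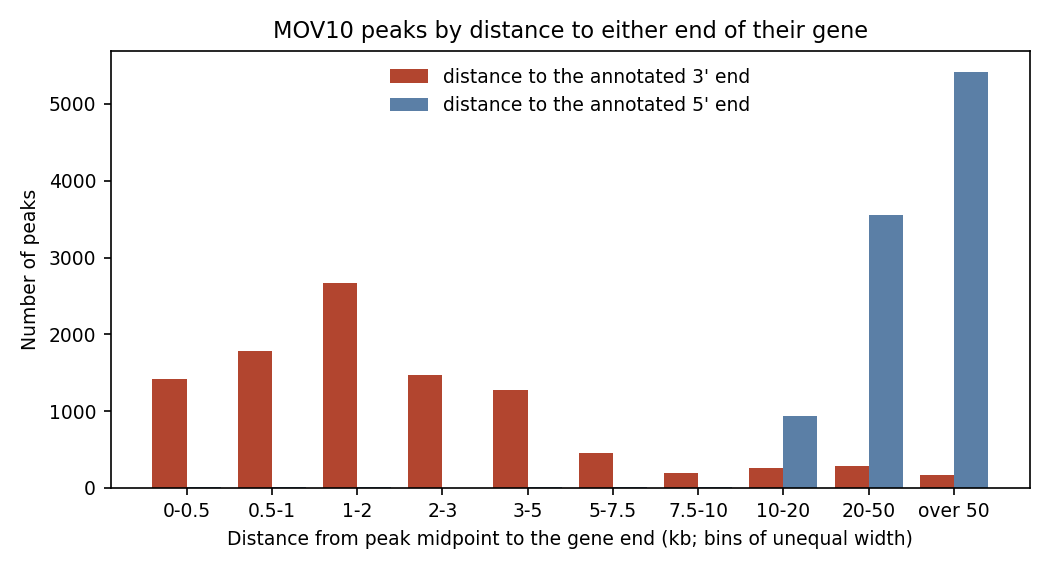
Number of MOV10 peaks (y axis) by distance in kb from the peak midpoint to the annotated 3′ end (red) and 5′ end (blue) of the gene, for 9978 peaks in 1421 genes of at least 15 kb, in bins of unequal width. The fullest bin by 3′ distance is 1 to 2 kb with 2670 peaks, while 31 peaks in all lie within 5 kb of a 5′ end.

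The strength of enrichment did not separate 3′-end peaks from the other peaks across genes. The median log2 fold enrichment was 3.73 for the 8620 peaks within 5 kb of the 3′ end and 3.71 for the 1358 peaks elsewhere. The difference was 0.017 (bootstrap interval over genes −0.16 to 0.17, two-sided permutation p = 0.54). Among peaks with −log10 p of at least 5 the sign turned, to −0.031 (permutation p = 0.25). Within single genes the picture differed. In the 139 genes that held both kinds of peak, the median of the 3′-end peaks exceeded that of the other peaks in 103. The mean difference over all 139 genes was 0.28 (interval 0.20 to 0.36, two-sided permutation p within genes = 0.001, the smallest that 2000 permutations can give). This within-gene comparison was chosen after the data had been seen.

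The strongest enrichment was at the 3′ end of Elavl1 on chromosome 8 (4284781 to 4325140, minus strand, GRCm38). Its leading peak, at 4285993 to 4286086, lay 1258 nt from the 3′ end and had a log2 fold enrichment of 6.93 and a −log10 p of 165. All 78 peaks of Elavl1 lay between 622 and 4752 nt from the 3′ end. Tead1 on chromosome 7 (112679356 to 112906784) reached 6.62 at 112902055 to 112902082, with 47 of its 68 peaks within 5 kb of the 3′ end. Nova2, a neuronal splicing regulator, reached 6.44 on chromosome 7 (18960932 to 18960939), 4384 nt from the end. Gna13, the α13 subunit of a trimeric G protein, reached 6.29 on chromosome 11 (109400679 to 109400750), and all 43 of its peaks lay within 5 kb of the end. Mib1 reached 6.28 on chromosome 18 (10815346 to 10815357). Ago2, which encodes the Argonaute protein of microRNA and siRNA silencing, reached 6.19 on chromosome 15 (73104144 to 73104188), 2541 nt from the end of the gene, and 42 of its 44 peaks lay within 5 kb of that end. Gfpt1, the first enzyme of hexosamine synthesis, reached 6.15 on chromosome 6 (87090890 to 87090931). In Cbx5 on chromosome 15, 67 of 110 peaks lay within 5 kb of the 3′ end. The strongest, 6.48, was at 103198220 to 103198226, 6677 nt from the end. The nearest lay 215 nt from the end. A single peak, the weakest of the gene at 3.49, lay 21628 nt away, and all others lay within 7.811 kb.

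Some transcripts carried strong peaks more than 5 kb from the 3′ end. In genes of at least 15 kb, 1327 peaks (13.3%) lay more than 5 kb from both ends. Many of these were not far past the window, with 456 peaks at 5 to 7.5 kb and 188 at 7.5 to 10 kb from the 3′ end. Among those farther away were the peaks of Cntn5, a neural cell adhesion gene on chromosome 9. Its 6 peaks lay between 560063 and 563306 nt from the 3′ end, and the strongest, at 10197475 to 10197584, had a log2 fold enrichment of 6.33. Hipk2, a nuclear kinase gene on chromosome 6, reached 6.06 at 38696823 to 38696909, 9354 nt from the 3′ end. Of its 23 peaks 0 lay within 5 kb of that end, and the nearest was 7218 nt away. In Tcf20 all 65 peaks lay between 16832 and 48627 nt from the 3′ end, with the strongest, 5.95, at 82854125 to 82854193 on chromosome 15. Whether these positions are exonic or intronic was not determined. Within 5 kb of the 5′ end and nearer to it than to the 3′ end lay 83 peaks, 31 of them in genes of at least 15 kb and the others in shorter genes, where both ends are close. Bcl2l2, which encodes the survival protein Bcl-w, reached 4.99 at 2478 nt from its 5′ end, in a gene of 7.49 kb on chromosome 14. The strongest peak of Sox12, a transcription factor gene, had a log2 fold enrichment of 4.75 and that of Purb, a purine-rich element binding protein gene, 4.32. Pabpc1 on chromosome 15 (36595658 to 36609581) had 33 of its 60 peaks within 5 kb of the 3′ end and its strongest, 5.23, 7219 nt away from it.

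Few peaks had their midpoint in a non-coding RNA gene alone. Rny1, the gene of the small cytoplasmic Y1 RNA on chromosome 6 (47788070 to 47788180), had 3 peaks, the strongest at 4.54, all at the highest listed −log10 p. They may hold reads of near-identical copies. Outside the rule for named genes, the other non-coding RNA genes with a peak that lay in no second gene were the long non-coding RNA gene AU020206 with 2 and the signal recognition particle RNA gene Rn7s1 with 1. Non-coding genes inside or overlapping other genes were not assessed, since peaks shared between genes were not assigned. None of the 19 annotated long non-coding RNAs of the list fixed before the data were examined had a peak, Malat1 included. Mov10 itself, Fmr1, which encodes the fragile X protein FMRP, and Upf1, the helicase of nonsense-mediated decay, also had no peak.

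Transcripts of the silencing machinery itself were among those with MOV10 peaks. Of 31 genes of microRNA silencing, 12 held peaks, 242 in all. After Ago2, the strongest were the deadenylase genes Cnot6l (5.24, 21 peaks) and Cnot6 (5.10, 25 peaks), both of the CCR4-NOT complex, and Pabpc1. Lin28a, which blocks let-7 maturation, reached 4.87 with 16 peaks, Ago1 4.76 with 10 and Tnrc6b, a GW182 protein gene, 4.45 with 36. Ago3, Cnot8 and Tnrc6c had 1 peak each, at 3.05, 3.08 and 3.04. The median strongest log2 fold enrichment of the 12 genes was 4.60, against 3.85 in the other coding genes with peaks, a difference of 0.76 (bootstrap interval −0.33 to 1.31). The permutation p was 0.0087, and 0.087 after Benjamini-Hochberg adjustment over 10 lists, so the difference did not pass. The 12 genes held a median of 18.5 peaks against 3 in the other genes (permutation p = 0.00012, adjusted 0.0012 over 10 lists), in a measure added after the data had been seen. With touching peaks merged the medians were 10 and 3 (adjusted permutation p = 0.0058). Counting peaks with a log2 fold enrichment of at least 4 alone, the medians were 6.5 and 2 and the permutation test no longer passed (adjusted p = 0.32).

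Other lists of RNA-binding protein genes also had members with peaks. Of 59 genes of splicing and nuclear RNA-binding proteins, 15 had peaks, led by Elavl1, the splicing factor gene Srsf1 (5.20, 20 peaks), Celf1 (4.76, 39 peaks) and Hnrnpa0 (4.75, 11 peaks). Their median of 4.04 differed from the other genes by 0.18 (permutation p = 0.45, adjusted 0.56). Of 30 genes of mRNA decay and P-bodies, 7 had peaks, among them the translational repressor gene Pum2 (4.63, 8 peaks) and the decapping enzyme gene Dcp2 (4.20, 16 peaks), and their median differed by −0.26 (permutation p = 0.42, adjusted 0.56). Patl1, a decapping activator, had 3 peaks up to 3.69, and Ythdf3, a reader of N6-methyladenosine, had 1 at 3.60. Among 63 RNA helicase genes, peaks were found in 4, too few to be tested, among them Ddx6 (4.19, 22 peaks), Ddx21 (3.94) and Ddx19b (3.64).

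Neuronal transcripts were represented by genes of the cytoskeleton, of adhesion and of synapses. Of 40 genes of cytoskeleton and neurite outgrowth, 14 had peaks. The collapsin response mediator genes Dpysl3 (5.47, 52 peaks) and Dpysl2 (5.28, 24 peaks) and the microtubule-associated protein genes Map2 (5.37, 15 peaks) and Mapt (5.33, 20 peaks) led the list, and all peaks of these 4 genes lay within 5 kb of the 3′ end. Of 51 brain mRNAs known as FMRP targets, 18 had peaks, led by the kinesin gene Kif1b (5.54, 35 peaks) and the kinase gene Wnk1 (5.43, 25 peaks), and the synaptic adhesion gene Nrxn2 reached 4.40. Of 40 adhesion and axon guidance genes, 10 had peaks, led by the semaphorin receptor gene Plxna1 (4.86, 11 peaks), the netrin receptor gene Unc5c (4.67, 13 peaks), Tenm4 (4.47, 10 peaks) and Cadm1 (4.40, 14 peaks). Cadm1 was an exception in position, with its peaks 9062 to 11103 nt from the 3′ end. The medians of these lists differed from the other genes with peaks by −0.015, 0.031 and 0.54, and none passed the permutation test (adjusted p = 0.94, 0.94 and 0.25). All of these signs turned when peaks with a log2 fold enrichment of at least 4 alone were used. Of 24 sympathetic and neuroblastoma lineage genes, 2 had peaks, Ret with 2 up to 3.18 and Gata2 with 1 at 3.17.

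Regulators of chromatin, growth and translation formed the remaining groups of size. Chromatin and transcription regulators had peaks in 20 of 44 genes, led by the DNA methyltransferase gene Dnmt3a (5.24, 36 peaks), the Polycomb gene Suz12 (4.84, 13 peaks), the chromatin remodelling gene Smarcc1 (4.80, 22 peaks) and the methylcytosine dioxygenase gene Tet3 (4.60, 28 peaks). Cell cycle and growth genes had peaks in 9 of 39, among them the kinase inhibitor gene Cdkn1a (4.80, 6 peaks), Ccnd3 (4.58, 2 peaks) and E2f1 (4.23, 6 peaks). Translation factors had peaks in 12 of 75, led by the eIF4E-binding protein gene Eif4ebp2 (5.38, 20 peaks), then Pabpc1, Eif4h (4.43, 13 peaks) and Eif4b (4.41, 28 peaks). Ubiquitin ligases and deubiquitinases had peaks in 16 of 127, led by Cbl (5.51, 10 peaks), Usp31 (5.22, 41 peaks), Usp12 (4.46, 16 peaks) and Itch (4.40, 2 peaks). Not counted were 3 further genes of this list and 2 translation factor genes with peaks only where genes overlap. Median differences were 0.32, 0.30, −0.26 and −0.36 in that order, and the permutation test passed for none (adjusted p = 0.33, 0.56, 0.54 and 0.25). The sign for chromatin regulators turned at a log2 fold enrichment of at least 4.

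**Figure D2:**
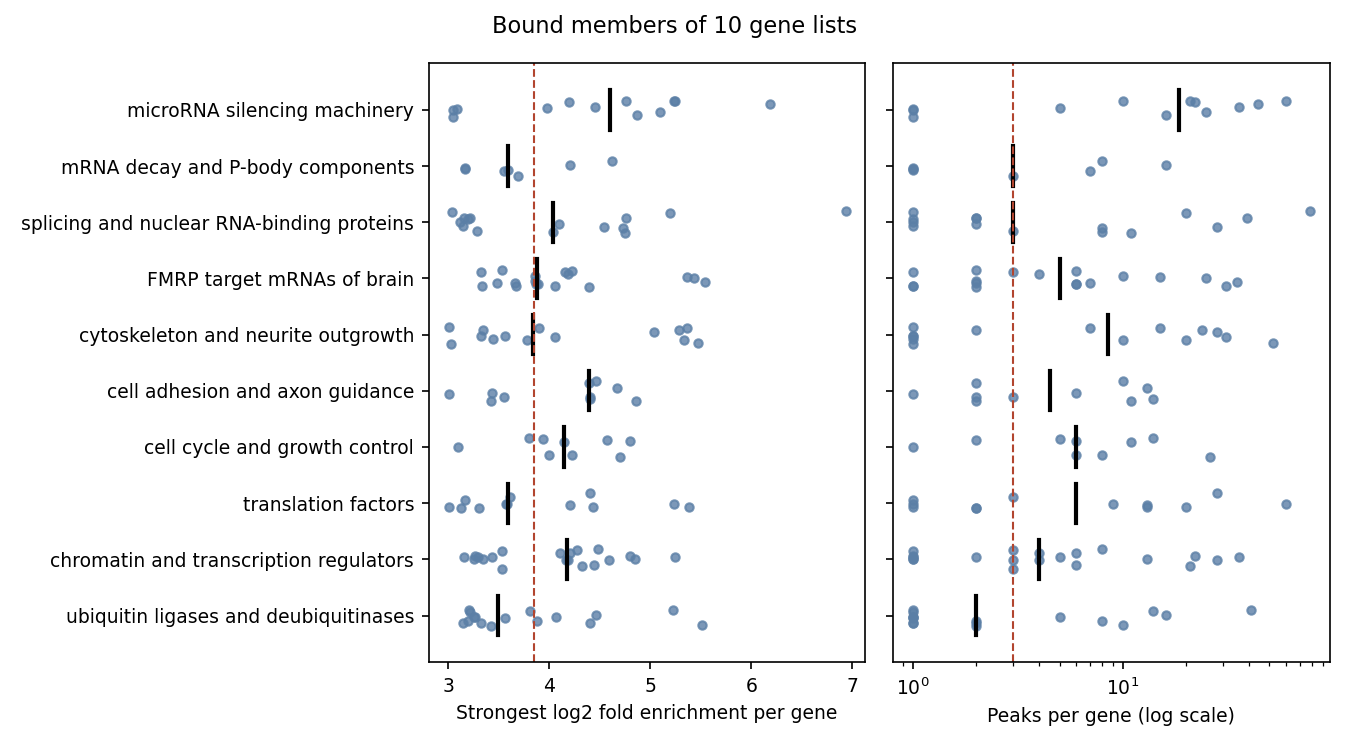
Strongest log2 fold enrichment per gene (left) and number of peaks per gene on a log scale (right) for the members with peaks of the 10 gene lists tested. Each point is a gene and the black bar is the median of the list. The dashed line is the median of the coding genes with peaks outside the microRNA silencing list (left 3.85, right 3). The microRNA silencing list stands at medians of 4.60 and 18.5.

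Among the lists with too few members with peaks to be tested were several of housekeeping genes. Of 84 cytosolic ribosomal protein genes, 4 had peaks, Rpsa with 10 up to 4.56, Rplp0 with 2 up to 4.10, Rpl22 with 4 up to 3.51 and Rpl15 with 1 at 3.26. These families have many processed pseudogenes, so their reads can be shared with near-identical copies. Of 85 nuclear genes of oxidative phosphorylation, 4 had peaks, Atp5j2 (4.54), Cox7a2l (3.63), Sdha (3.58) and Sdhc (3.02). Histone genes had peaks in 1 of 77, H3f3b, with 7 peaks up to 3.77, a variant histone gene named after its values were seen. In the list of small nuclear and nucleolar RNAs and their hosts, 2 of 181 genes had peaks, Rny1 and Rn7s1. These are the genes of Y1 RNA and of signal recognition particle RNA, so neither is of the classes that name the list. Another 1 of its members had peaks only where genes overlap. Of 2 mitochondrially encoded genes listed, 0 had any. Of 30 interferon-stimulated and innate immune genes, a further list not tested, 4 had peaks, Trim25 (4.68, 10 peaks), Trim56 (3.56), Samhd1 (3.43) and Zc3hav1 (3.26). The value of Trim56 is that of the 1 peak inside its annotated span, while 16 peaks of up to 4.55 lay past its annotated end. How abundant each transcript was in the input was not known, so shares of genes with peaks describe the list of peaks and were not tested between groups.

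The test on the position of peaks also set no list apart. Counted here were genes with at least 1 peak within 5 kb of the 3′ end and no nearer to the 5′ end. Of the coding genes with peaks outside the microRNA silencing list, 92.8% had such a peak, and in that list 10 of 12 did (Fisher's exact p = 0.21, adjusted 0.71). For 0 of 10 lists did this share differ after adjustment. With so high a share in the other genes, this test could hardly find a list with a higher one. Among splicing and nuclear RNA-binding proteins 15 of 15 genes had such a peak (Fisher's exact p = 0.62). In genes shorter than 5 kb, any peak at least as near to the 3′ end as to the 5′ end counts as such a peak. In the test of the strongest enrichment 0 of 10 lists passed the adjusted permutation test, and 1 had an unadjusted p under 0.05. In simulated lists of 12 genes this test, without adjustment, called a log2 shift of 0.5 in 38.0% of runs and a shift of 1.0 in 95.5%. Adjustment over 10 lists was not simulated and can only lower these rates, so shifts of the size seen here could be missed.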

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

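The 2 kb and 10 kb windows, the assignment among coding genes alone, the merging of touching peaks, the removal of the 10 genes with most peaks, the comparison within genes and all tests of peaks per gene were chosen after the data had been seen. The share of peaks near the 3′ end passed the permutation test under all 9 alternatives, at 58.8% for 2 kb (4.20% by random placement), 92.8% for 10 kb (21.0%) and 85.9 to 90.0% under the others. The count of 12236 peaks became 4128 with a log2 fold enrichment of at least 4, 8042 with touching peaks merged and 6307 with peaks within 50 nt merged, since merging joins neighbours. The difference in log2 fold enrichment by position changed from 0.017 to −0.031 at a −log10 p of at least 5, and to 0.28 within genes holding both kinds of peak, and the cause was not tested. No gene list passed for strongest enrichment under the 3 alternatives run, but several differences that had not passed changed sign. At a log2 fold enrichment of at least 4 the difference became 0.80 for cytoskeleton (6 members), −0.075 for adhesion, −0.13 for chromatin regulators and −0.20 for FMRP targets. With the median over the peaks of a gene it became −0.029 for splicing and nuclear RNA-binding proteins and −0.0039 for chromatin regulators, and with assignment among coding genes 0.043 for cytoskeleton. Leaving out each member of the microRNA silencing list gave differences of 0.60 to 0.91 and medians of 16 to 21 peaks per gene. At a log2 fold enrichment of at least 4 its median of 18.5 peaks became 6.5 and no longer passed, with 8 members left, and with touching peaks merged it became 10 and passed. No paired analysis was possible because the list gives 1 value per peak over both replicates, so leaving out a replicate was not run either. Region priority, transcript models and all tests of sequence were not run, as exons and a genome were not used here.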

Other observations

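The tests of chromosomes and of peaks beyond annotated gene ends were chosen only after those results were seen. Peaks were spread unevenly over chromosomes. Of the coding genes on chromosome 15, 11.7% had a peak (Fisher's exact test, adjusted p = 0.000621 over 20 chromosomes), and on chromosome 11 the share was 11.1% (exact test, adjusted p = 1.24e-05). On chromosome 7 it was 4.29% (exact test, adjusted p = 8.04e-10). Whether these shares follow the number of expressed genes was not tested. Genes with peaks had a median span of 43.4 kb, against 17.1 kb over all coding genes of the annotation. Pseudogenes held 11 peaks in 7 genes, and transcribed pseudogenes 2 peaks in 2 further genes. Of these, Rpsa-ps10 on chromosome 3 had 3, with 10 in its parent gene Rpsa, while Ftl1-ps1 on chromosome 13 had 2 with 0 in Ftl1, the ferritin light chain gene. Reads can be shared between near-identical copies, and only peaks lying in a single gene were counted. These counts therefore do not show which copy was bound.

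Peaks with their midpoint outside annotated genes lay, for the larger part, past the 3′ end of a gene that had peaks of its own. Of 274 such peaks, 176 (64.2%, exact 95% interval 58.2 to 69.9) had a gene with peaks on the same strand ending within 10 kb upstream, and 2 (0.730%, interval 0.0885 to 2.61) had one starting within 10 kb downstream. They fell behind 15 genes and clustered there, so they are not independent and the interval is too narrow. Zfp652, a zinc finger gene on chromosome 11, had 3 peaks inside its annotated span and 37 beyond its end, up to 7574 nt away and as strong as 5.40. Abhd2 on chromosome 7 had 2 inside and 28 beyond, and Trim56 1 and 16. Ago2 had 44 inside and 26 beyond, as far as 5521 nt and as strong as 6.15, and Sv2c, a synaptic vesicle protein gene, 22 and 17. Joined into 39 clusters by gaps of up to 10 kb on a strand, 15 had such a gene upstream, 1 had one downstream and 23 had neither (two-sided exact binomial p = 0.00052 for 15 against 1). Of these 23 clusters, 20 had another coding gene within 10 kb on the upstream side and 12 had one on the downstream side, 10 of them on both, with the strand of these genes not known. A hypothesis, drawn from the same data, is that 3′ ends longer than those of the gene table are used and may carry MOV10, which was not tested against other annotation.

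Genes with more peaks also held stronger peaks. Across the 1686 coding genes with peaks, which are not independent replicates, Spearman's rho between the number of peaks and the strongest log2 fold enrichment was 0.786. A gene with more peaks has more chances of a high one, and permuting enrichments over all peaks 1000 times gave a mean rho of 0.672 and a highest of 0.709. The median enrichment per gene, which has no such advantage, had a rho of 0.457 with the number of peaks, against at most 0.0652 under permutation. More draws alone therefore do not account for the relation. Only peaks above a lower limit of enrichment were listed, so a gene with stronger enrichment can pass more peaks and also have a higher median. Part of the relation can thus be built in, and permuting the listed peaks does not remove this. Transcript abundance in the input, which sets how easily a weak peak is found, also stays open. So does the splitting of broad sites into touching peaks, and no biological explanation was tested.

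The higher median enrichment of the microRNA silencing genes went with their number of peaks. Against random sets of other genes, each drawn from the 40 genes closest to a member in number of peaks, the difference in median strongest log2 fold enrichment of 0.76 became −0.076 (two-sided permutation p = 0.73 from 20000 random draws of matched genes). As peaks were listed only above a log2 fold enrichment of 3, the number of peaks itself follows enrichment, so this fall is largely built in and does not show that the number of peaks is the cause. Matched in the same way on gene span it was 0.72 (permutation p = 0.0057). The median spans were 39.8 kb in the list and 43.5 kb in the other genes, so this matching had no longer span to remove. The median spans themselves argue against longer gene spans as the source of the difference in these genes, and the matching on span adds nothing to this. The length of mature transcripts was not taken into account. The matching on number of peaks decides nothing. The unmatched difference itself did not pass adjustment over 10 lists, and why these genes hold a median of 18.5 peaks was not tested.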
